A study of Homo sapiens with 8 samples.

How the data were processed

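Gene expression was measured with Affymetrix Human Gene 1.0 ST arrays on RNA from HepG2 cells, a human liver tumour line with hepatocyte features. The cells had been kept for 4 h in DMSO at 0.1%, in JQ1 at 500 nM or in RVX-208 at 5000 nM. The 8 arrays used here are 3 of DMSO, 2 of JQ1 and 3 of RVX-208; a further JQ1 sample, which the study design mentions, is not analysed here. The labels number the samples within each group. They do not say whether samples of a group were separate cultures, and the labels used here hold no hybridisation dates or batches.

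The table deposited by the authors holds log2 values per transcript cluster, which the submitters' processing notes trace to RMA (background correction, quantile normalisation over arrays and summary of probes), with R 2.15.3 and limma 3.14.4. The values ran from about the same minimum to the same maximum in every array and matched that scale. A deposited table of the authors' limma fit gives log2 fold changes, an F score and its p-value with the adjusted p-value per probe set. It was used only to check the scale and the sample mapping: its log2 fold changes equalled differences of group means of the log2 values within 1e-04 for 19815 of 19816 probe sets. The sources used here do not state which filter led to the 19816 probe sets, and they hold no detection calls. Signals on arrays carry no count, so the number of arrays limits the precision; dim probe sets lie closer to background and their fold changes are compressed.

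Of the 19816 probe sets, 17859 were paired with 1 gene symbol, 997 with several genes and 960 with none. The last 2 kinds were left out of the gene tests. For 14 genes with more than 1 probe set, the one with the highest mean over all arrays was used, which left 17845 genes. The gene identifiers of 17835 of the probe sets with 1 gene matched the reference gene names, and 24 did not; 0 symbols had to be updated. No genome coordinates were used, and genes are given by symbol and probe set number.

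Fits were made with limma 3.58.1 in R 4.3.3, and tables and plots with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. A single linear model with a mean per group (lmFit, then eBayes at its default settings) was fitted over all 8 arrays, so that the spread was shared by the 3 groups; its moderated test had 8.55 degrees of freedom. The comparisons were JQ1 against DMSO, RVX-208 against DMSO, and JQ1 against RVX-208, each two-sided. Adjusted p-values are Benjamini-Hochberg values over the 17845 genes, and a gene was called at an adjusted p under 0.05 with no fold minimum. Errors are standard errors (SE) of the fitted log2 fold change unless given as SD, and intervals are 95% confidence intervals. The replicates are not stated to be separate cultures, so p-values measure the spread between these samples.

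The comparisons, the gene lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined. The 29 lists had 581 entries, of which 512 were matched to a tested gene, 25 were only on probe sets shared by several genes and 44 are not analysed here. Each list was tested against all other genes with limma's camera at its preset correlation between genes, adjusted over the 29 lists of a comparison, and again with a correlation estimated per list. The rotation test fry was also run; it asks whether genes of a list move, on balance, one way, and does not compare the list with other genes. The named genes are the 10 largest rises and 10 largest falls against DMSO per compound, the 5 largest each way between the compounds, up to 2 highest and 2 lowest members of each list against DMSO, and APOA1, MYC, HEXIM1, SERPINI1, BRD2 and BRD3 in every comparison. For the first 3 of these parts a gene had to be called and all its treated arrays had to lie beyond all arrays of the other group. Other list members are named where they illustrate a list, and those were picked after their values were seen.

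Both compounds were compared with the same 3 DMSO arrays, so fold changes of JQ1 and RVX-208 share noise. The covariance across genes was therefore set against 1000 simulated data sets with no effect and the same shared controls, and the share of JQ1 calls with the same sign in RVX-208 against 100 simulated data sets with an effect of JQ1 alone. Noise was drawn for each gene on its own. Noise that many genes share is thus not in these simulations, and their range may be too narrow. The 3 DMSO arrays cannot be divided into parts of 2.

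The steps were tested on simulated data with the fitted spread, in 20 simulations of 17845 genes with 200 changed genes each. For JQ1 against DMSO 21.7% of the genes changed by 0.3 log2 units, 90.1% of those changed by 0.6 and 98.8% of those changed by 1 were recovered; for RVX-208 against DMSO the shares were 36.2%, 95.1% and 99.4%. False calls made up 5.23% and 6.45% of all calls. The histone list, shifted by 0.2 log2 units, was called in 20 of 20 simulations for each compound.

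The alternatives were testing every probe set on its own, leaving out the 40% of genes with the lowest mean (10707 genes left), centring each array on its median or on the listed housekeeping genes, quantile normalisation again, an intensity trend with robust variance estimates, array weights, only the groups compared, a block for the replicate number, other thresholds, the other gene set tests, and leaving out each array in turn. When a JQ1 array is left out, the spread of the remaining one is taken from the other groups. Cyclic loess normalisation was added after the distributions of the arrays had been seen.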

Results

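Transcript levels were measured in HepG2 cells after 4 h with 1 of 2 inhibitors of the BET proteins, which bind acetylated lysines of chromatin through paired bromodomains. JQ1 is a thienotriazolodiazepine that binds both bromodomains of the BET proteins. RVX-208 (apabetalone) is a quinazolone with a preference for the second bromodomain, developed for its effect on apolipoprotein A-I. The doses differed, 500 nM for JQ1 and 5000 nM for RVX-208. The set held 3 DMSO, 2 JQ1 and 3 RVX-208 arrays. The median log2 signal of the arrays lay between 7.26 and 7.31, and replicate arrays correlated across probe sets at r between 0.9962 and 0.9973. The first principal component took up 45.2% of the variance and ordered the groups, with DMSO arrays at −16.44 to −12.96, RVX-208 arrays at −0.73 to 2.65 and JQ1 arrays at 19.99 and 20.30. The second took up 18.4% and set RVX-208 arrays (−13.53 to −7.99) apart from DMSO (0.61 to 12.11) and JQ1 arrays (9.43 and 4.51). Its extremes were DMSO replicate 3 and RVX-208 replicate 3. Whether it reflects RVX-208 or a difference between arrays was not tested. The probe sets of the genes set out first were 8007745 for HEXIM1, 8179504 for BRD2, 8164995 for BRD3, 8148317 for MYC, 8083779 for SERPINI1, 7951865 for APOA1, 8124492 for H2BC12 and 7990391 for CYP1A1. The number of arrays limits the precision of each value.

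JQ1 against DMSO asks which transcripts respond to the broad BET inhibitor. JQ1 raised HEXIM1, the inhibitor of the elongation kinase P-TEFb, 2.81-fold (log2 fold change 1.49 ± 0.06 SE, n = 2 and 3, adjusted p = 9.942e-06), from a mean log2 signal of 9.65 ± 0.04 SD to 11.14 ± 0.08. It raised a group of histone genes, among them H2BC12 by 1.58 ± 0.13 and H2BC5 by 1.32 ± 0.12 log2 units, and BRD2 itself by 1.01 ± 0.07. MYC, the growth-promoting transcription factor, fell by 0.67 ± 0.06 (adjusted p = 1.629e-04). As lists, hepatocyte transcription factors (10 of 21 members down, 1 up), ribosome biogenesis genes (12 of 22 down) and bile acid genes (6 of 18 down, 1 up) were lower at the preset correlation of camera, with adjusted p = 0.291, 0.291 and 0.114 with an estimated correlation.

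In all, 4066 of 17845 genes were called, 1916 higher and 2150 lower, which is 22.8% of the genes tested. Of these, 667 changed at least 1.5-fold and 109 at least 2-fold. JQ1 arrays lay wholly above or below the DMSO arrays for 9002 genes, 50.4% of those tested against 20% by chance. The largest rises among called genes were those of RALGAPA1 (2.21 ± 0.59), SLFN5 (2.06 ± 0.11), ARRDC4 (1.87 ± 0.08) and KRCC1 (1.80 ± 0.09). They were followed by ZSWIM6 (1.71 ± 0.05), HLA-DOB (1.69 ± 0.48), CNNM4 (1.66 ± 0.05), H2BC12, the RNA-editing enzyme gene ADARB1 (1.55 ± 0.07) and TXNIP (1.53 ± 0.06). ARRDC4 and TXNIP encode arrestin-domain proteins that limit glucose uptake. The largest falls were those of the EGF-family ligand gene EREG (−1.90 ± 0.17), ART4 (−1.89 ± 0.10), MAB21L3 (−1.84 ± 0.09) and PALMD (−1.69 ± 0.08). TNS4 (−1.52 ± 0.07), GPAM (−1.44 ± 0.07), the noncoding LINC00652 (−1.43 ± 0.29), the lactate receptor gene HCAR1 (−1.43 ± 0.09), VPS52 (−1.37 ± 0.26) and C3orf33 (−1.36 ± 0.07) came next. GPAM encodes the enzyme of the first step of triglyceride synthesis. The call of RALGAPA1 held in 4 of 8 fits without 1 array, with adjusted p = 0.0716 without DMSO replicate 1 and 0.0562 without DMSO replicate 2. Its estimate was 1.990 without JQ1 replicate 2, against 2.21 with all arrays. HLA-DOB stood at 0.692 without JQ1 replicate 1 (adjusted p = 0.120), and its call was also lost without DMSO replicate 1 (0.0895), 2 (0.0739) or 3 (0.0581) and RVX-208 replicate 1 (0.0515). LINC00652 reached 0.0705 without JQ1 replicate 2. The number of called genes was 2572 without JQ1 replicate 1 and 2565 without JQ1 replicate 2.

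Of 29 fixed gene lists, 11 were called against DMSO by camera at its preset correlation, 8 higher and 3 lower. With a correlation estimated per list none was called, with an unadjusted p under 0.05 for 6 lists, and fry called 16. This correlation was below 0 for bile acid genes (−0.034) and immediate early genes (−0.011), and above 0 for the other called lists. The unadjusted camera p of these 2 lists still rose, from 9.134e-04 to 0.0158 and from 1.820e-04 to 0.00905. A positive correlation between genes is therefore not what ended these 2 calls. Other list or family calls that were lost with an estimated correlation are likewise not put down to correlation between genes alone. The histone list held 13 of 17 members higher and 0 lower (14 and 0 when adjusted over the list alone; adjusted p = 1.502e-09, and adjusted p = 0.0875 with an estimated correlation). Besides H2BC12 and H2BC5, its members included H2BC8 (0.96 ± 0.08) and H2BC4 (0.81 ± 0.07). Of 8 reporter genes known to rise with BET inhibitors, 7 rose, among them SERPINI1 (0.93 ± 0.16), and 1 fell, over all genes and when adjusted over the list alone (adjusted p = 3.115e-05, and 0.0875 as an adjusted p with an estimated correlation). The gene that fell was ZMYND8, a reader of acetylated histones, at −0.87 ± 0.05. Of 8 reporters known to fall, MYC, FOSL1 (−0.42 ± 0.08) and CDK6 (−0.32 ± 0.07) fell and 5 did not pass, with 3 lower also when adjusted over the list alone; the list was not called (adjusted p = 0.316). FOSL1 had an adjusted p of 0.0593 without JQ1 replicate 2.

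The list of P-TEFb, elongation and BET genes had 9 of 22 members higher and 2 lower (10 and 2 when adjusted over the list alone), with a median of 0.105 that went to −0.053 when arrays were centred on housekeeping genes (adjusted p = 0.00121, and adjusted p = 0.146 with an estimated correlation). POLR2A, the largest subunit of RNA polymerase II, rose by 0.85 ± 0.07 and CCNT1, the cyclin of P-TEFb, by 0.72 ± 0.07. The members that fell were HEXIM2 (−0.83 ± 0.07), a paralog of HEXIM1, and NELFA (−0.62 ± 0.05), a subunit of the negative elongation factor. BRD3 stood at 0.02 ± 0.05 (adjusted p = 0.841). Immediate early genes were higher as a list, with 10 of 23 up and 1 down (11 and 1 when adjusted over the list alone; adjusted p = 0.00112, and adjusted p = 0.0875 with an estimated correlation). EGR1 (0.62 ± 0.07), JUND (0.55 ± 0.07), the MAPK phosphatase gene DUSP6 (0.47 ± 0.06) and MCL1 (0.47 ± 0.06) rose, and FOSL1 was the member that fell.

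Ribosome biogenesis genes were lower, with 12 of 22 members down and 0 up (14 and 0 when adjusted over the list alone; adjusted p = 3.115e-05, and adjusted p = 0.291 with an estimated correlation). RRS1 (−0.58 ± 0.06), WDR43 (−0.55 ± 0.05) and NOP16 (−0.53 ± 0.06) showed the lowest values. Among hepatocyte transcription factors 10 of 21 fell and 1 rose, both over all genes and when adjusted over the list alone (adjusted p = 0.00112, and adjusted p = 0.291 with an estimated correlation). PROX1 fell by 1.11 ± 0.10, HNF4G by 0.99 ± 0.06 and TBX3 by 0.54 ± 0.06. HHEX was the member that rose (0.19 ± 0.05), with adjusted p = 0.128 without JQ1 replicate 1, 0.0853 without JQ1 replicate 2, 0.0594 and 0.0687 without DMSO replicate 1 and 3, and 0.0520 without RVX-208 replicate 2. Bile acid genes had 6 of 18 members lower and 1 higher (8 and 1 when adjusted over the list alone; adjusted p = 0.00294, and adjusted p = 0.114 with an estimated correlation). BAAT, which conjugates bile acids, fell by 1.01 ± 0.07, the exporter gene SLC51B by 0.62 ± 0.09, AKR1D1, a reductase of bile acid synthesis, by 0.59 ± 0.06, and the canalicular transporter gene ABCC2 by 0.52 ± 0.06. NR0B2, the corepressor that acts on bile acid synthesis, rose by 0.32 ± 0.10, with 0.194 and adjusted p = 0.282 without JQ1 replicate 1, and adjusted p = 0.102 and 0.120 without DMSO replicate 2 and 3, and 0.0602, 0.0584 and 0.0669 without RVX-208 replicate 1, 2 and 3.

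Cholesterol synthesis genes had 8 of 19 members higher and 0 lower, over all genes and when adjusted over the list alone, with a median of 0.101 that went to −0.057 with housekeeping centring (adjusted p = 0.00121, and adjusted p = 0.291 with an estimated correlation). The isopentenyl diphosphate isomerase gene IDI1 rose by 0.91 ± 0.07, the sterol carrier gene STARD4 by 0.62 ± 0.09 and TM7SF2, a sterol reductase, by 0.60 ± 0.06. In the unfolded protein and integrated stress response list 10 of 22 members rose and 2 fell (11 and 2 when adjusted over the list alone; adjusted p = 0.00228, and adjusted p = 0.291 with an estimated correlation). HERPUD1 (0.60 ± 0.06), DNAJC3 (0.55 ± 0.07) and ATF4 (0.44 ± 0.06) rose, while TRIB3 (−0.82 ± 0.10), a pseudokinase induced by ATF4, and XBP1 (−0.44 ± 0.07), a transcription factor of the unfolded protein response, fell. Heat shock genes had 5 of 12 members up and 1 down (6 and 1 when adjusted over the list alone), with a median of 0.131 that went to −0.026 with housekeeping centring (adjusted p = 0.0295, and adjusted p = 0.488 with an estimated correlation); DNAJB1 rose by 0.73 ± 0.07 and HSPA4L fell by 0.36 ± 0.05. The heat shock call was kept in 10 of 17 alternative settings, with adjusted p = 0.0929 without JQ1 replicate 1 and 0.0611 without DMSO replicate 3. Housekeeping genes had 2 of 11 members higher, B2M (0.42 ± 0.06) and GUSB (0.22 ± 0.06), and 0 lower, also when adjusted over the list alone, with a median of 0.114 that went to −0.044 when these genes were used for centring (adjusted p = 0.00314, and adjusted p = 0.146 with an estimated correlation). That centring makes the mean of these genes equal in every array, so their own median near 0 is no test. It moved the median log2 fold change of all genes to −0.198 for JQ1 and −0.116 for RVX-208. Directions are therefore given relative to the normalisation by the authors.

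Other lists were not called with JQ1, although members moved. ABCA1, which loads lipid onto apolipoprotein A-I, fell by 0.64 ± 0.06 and APOA5 by 0.30 ± 0.06, the latter with an adjusted p of 0.0643 without JQ1 replicate 2; the other 15 of the 17 apolipoprotein and lipoprotein genes did not pass, the count when adjusted over the list alone being the same (list adjusted p = 0.781). The probe set of APOA1 was dim, with DMSO arrays at 4.05 to 5.31 and JQ1 arrays at 4.51 and 5.76, and its log2 fold change of 0.33 ± 0.57 had an interval of −0.98 to 1.64 (adjusted p = 0.727). The iron hormone gene HAMP fell by 0.98 ± 0.09, the only one of 21 acute phase genes to pass, also when adjusted over the list alone (list adjusted p = 0.339). The Wnt antagonist gene DKK1 fell by 1.23 ± 0.06 and RNF43 by 0.79 ± 0.06 in a Wnt target list with 5 of 15 members down and 3 up (6 and 3 when adjusted over the list alone; list adjusted p = 0.337). The cytokine gene LIF fell by 1.25 ± 0.15 in an NF-kB and cytokine list with 3 of 21 members down and 2 up, also when adjusted over the list alone (list adjusted p = 0.337). CYP1A1, a dioxin-inducible oxidase gene, fell by 1.22 ± 0.10 while TIPARP rose by 0.87 ± 0.07, each 1 of 2 that moved that way among 16 xenobiotic metabolism genes (3 lower and 2 higher when adjusted over the list alone; list adjusted p = 0.937). The remaining lists gave list adjusted p-values of 0.0567 for mitosis, 0.148 for fibroblast and stroma markers, 0.358 for G1/S genes and for p53 targets, and 0.453 for fatty acid synthesis. They were 0.468 for hypoxia and glycolysis, 0.498 for interferon response, 0.591 for blood cell markers, 0.690 for complement, coagulation, and TGF-beta and matrix genes, and 0.803 for oncofetal genes. The test pointed up while the median was below 0 for G1/S (median −0.015, mean 0.029), xenobiotic (−0.013, −0.085) and TGF-beta genes (−0.043, 0.014). It pointed up with a mean below 0 for apolipoprotein (median 0.047, mean −0.021), fatty acid (0.066, −0.025), complement (0.043, −0.008), acute phase (0.054, −0.013) and oncofetal genes (0.004, −0.046).

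**Figure D1:**
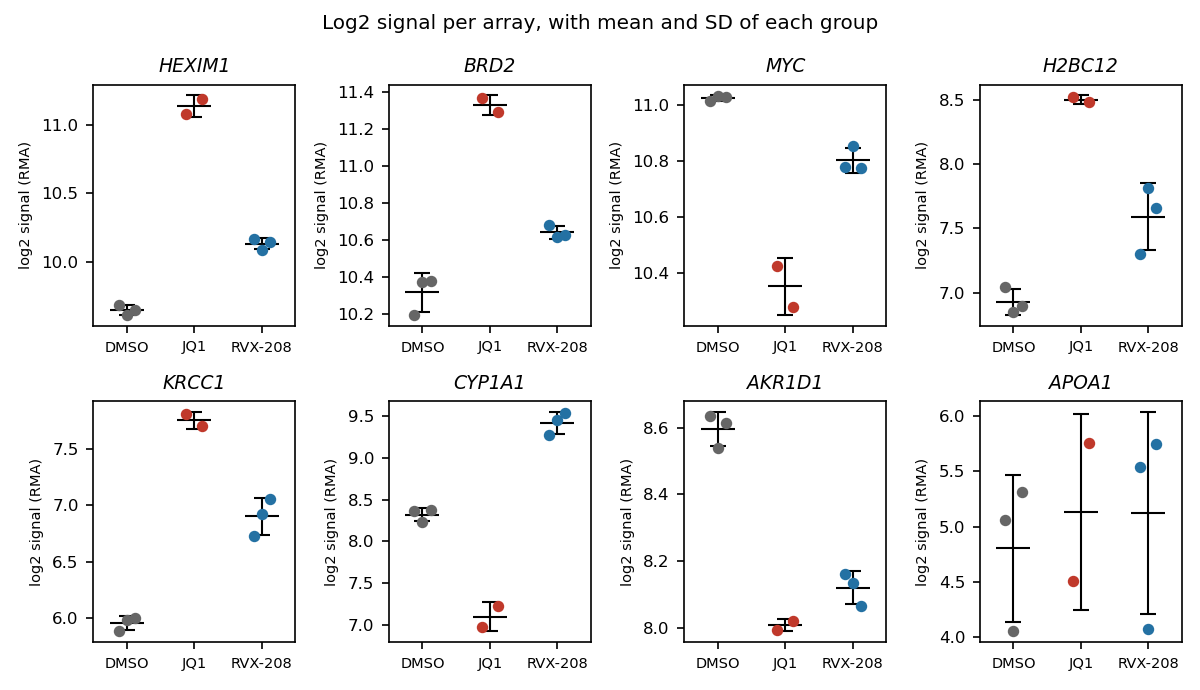
Log2 signal of 8 genes in each array of the DMSO, JQ1 and RVX-208 groups, with the group mean and its SD. HEXIM1 rose from a mean of 9.65 in DMSO to 10.13 with RVX-208 and 11.14 with JQ1, CYP1A1 went from 8.32 to 9.42 and 7.10, and the APOA1 arrays overlap between groups.

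RVX-208 against DMSO asks for the response to the inhibitor that prefers the second bromodomain. The largest rise was that of CYP1A1, 2.14-fold (log2 fold change 1.10 ± 0.09, n = 3 and 3, adjusted p = 0.00677), from a mean log2 signal of 8.32 ± 0.08 SD to 9.42 ± 0.13. HEXIM1 rose by 0.48 ± 0.05 (adjusted p = 0.00677), KRCC1 by 0.95 ± 0.08, the short-chain dehydrogenase gene DHRS2 by 0.86 ± 0.05 and the MYB-family gene MYBL1 by 0.68 ± 0.07. MAB21L3 fell by 0.82 ± 0.08, AKR1D1 by 0.47 ± 0.05 and the matrix glycoprotein gene THBS1 by 0.47 ± 0.05. As lists, histone, cholesterol synthesis and BET reporter genes were higher at the preset correlation of camera, with adjusted p = 0.170, 0.180 and 0.170 with an estimated correlation.

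RVX-208 gave 1120 called genes, 546 higher and 574 lower, or 6.28% of those tested. Of these, 41 changed at least 1.5-fold and 2 at least 2-fold, CYP1A1 and LINC00652 (−1.26 ± 0.26). The direction of the calls went with signal. For example, 10 genes were higher and 99 lower at mean log2 signals of 5.29 to 5.99, and 108 higher and 46 lower at 8.71 to 9.42. After cyclic loess normalisation 906 genes were called, 528 of them higher, and 734 of the 1120 calls were kept in the same direction. The groups did not overlap for 6080 genes, 34.1% of those tested against 10% by chance. Other rises named by rule were those of SRP9 (0.78 ± 0.12), ZNF737 (0.69 ± 0.13), SLFN5 (0.68 ± 0.10), H2BC12 (0.66 ± 0.12), RPS28 (0.66 ± 0.13) and ZNF43 (0.65 ± 0.09). Other falls were those of CDK11B (−0.99 ± 0.23), ZNF208 (−0.82 ± 0.20), TATDN1 (−0.79 ± 0.12), TBX4 (−0.72 ± 0.13), PCDHA13 (−0.69 ± 0.14), SH3TC2 (−0.63 ± 0.07), FAM169BP (−0.63 ± 0.12) and MOG (−0.63 ± 0.13). Many calls were lost when 1 array was left out (ZNF208 was called in 0 of 8 such fits). The count was 52 without RVX-208 replicate 3, 81 without DMSO replicate 3 and 151 without RVX-208 replicate 2. It was 291 without RVX-208 replicate 1, 310 without DMSO replicate 2 and 705 without DMSO replicate 1. Of the 53 genes named by rule and called, 10 were still called without RVX-208 replicate 3, 14 without RVX-208 replicate 2 and 16 without DMSO replicate 3. The number was 23 without DMSO replicate 2, 24 without RVX-208 replicate 1, 28 without DMSO replicate 1 and 43 without JQ1 replicate 1 or 2. With the threshold kept at an adjusted p under 0.05, 9 of them were called in every other alternative and every fit without 1 array. They were CYP1A1, KRCC1, DHRS2, MYBL1, HEXIM1, MAB21L3, SH3TC2, AKR1D1 and THBS1.

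With RVX-208, 10 of the 29 lists were called, 5 higher and 5 lower. None was called with an estimated correlation, where 6 had an unadjusted p under 0.05; fry called 14. Histone genes had 8 of 17 members higher and 0 lower (12 and 0 when adjusted over the list alone; adjusted p = 2.111e-07, and adjusted p = 0.170 with an estimated correlation), among them H2BC5 (0.63 ± 0.11), H2BC4 (0.59 ± 0.06) and H2BC21 (0.53). Cholesterol synthesis genes had 5 of 19 members higher and 0 lower (10 and 0 when adjusted over the list alone; adjusted p = 1.191e-05, and adjusted p = 0.180 with an estimated correlation). They were IDI1 (0.45 ± 0.07), STARD4 (0.34 ± 0.08), MSMO1 (0.34 ± 0.06), SC5D (0.30 ± 0.06) and TM7SF2 (0.24 ± 0.05). STARD4 was called in 0 of 8 fits without 1 array (0.323 and adjusted p = 0.138 without RVX-208 replicate 3). Of the 8 BET reporters known to rise 5 rose and 0 fell (6 and 0 when adjusted over the list alone; adjusted p = 1.340e-04, and adjusted p = 0.170 with an estimated correlation); SERPINI1 did not pass (0.38 ± 0.15, adjusted p = 0.140), nor did ZMYND8 (−0.08 ± 0.05). Of the 8 reporters known to fall MYC alone passed, also when adjusted over the list alone, and that list was not called (adjusted p = 0.183). The reporters known to rise and the histone list share 4 genes, H2BC12, H2BC5, H2BC21 and H1-2, and are not separate evidence. These 3 lists were called in all 17 settings tried at the preset correlation. BRD2 rose by 0.33 ± 0.06 and MYC fell by 0.22 ± 0.05 (adjusted p = 0.0482), and both calls were lost in fits without 1 array. The estimates changed little, to 0.332 and −0.209 without RVX-208 replicate 3, where the adjusted p was highest. Without RVX-208 replicate 1, 2 and 3 and DMSO replicate 2 and 3 the adjusted p of BRD2 was 0.0691, 0.0702, 0.0931, 0.0538 and 0.0679. The adjusted p of MYC was 0.106, 0.0878 and 0.153 without RVX-208 replicate 1, 2 and 3, and 0.0767, 0.105 and 0.119 without DMSO replicate 1, 2 and 3.

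Bile acid genes were lower with RVX-208, with SLC51B (−0.49 ± 0.08) and AKR1D1 the 2 of 18 members that fell and 0 that rose (7 and 0 when adjusted over the list alone; adjusted p = 0.0228, and adjusted p = 0.180 with an estimated correlation). Ribosome biogenesis genes had 2 of 22 lower, NOP16 (−0.27 ± 0.05) and MYBBP1A (−0.19 ± 0.05), and 0 higher (6 and 0 when adjusted over the list alone; adjusted p = 0.0228, and adjusted p = 0.438 with an estimated correlation). Hepatocyte transcription factors had 2 of 21 lower, CREB3L3 (−0.28 ± 0.05) and ONECUT1 (−0.26 ± 0.05), and 0 higher (4 and 0 when adjusted over the list alone; adjusted p = 0.0429, and adjusted p = 0.438 with an estimated correlation). The NF-kB and cytokine list had 3 of 21 lower, LIF (−0.59 ± 0.14), the NF-kB inhibitor gene TNFAIP3 (−0.30 ± 0.05) and the chemokine gene CXCL5 (−0.27 ± 0.06), and 0 higher (4 and 0 when adjusted over the list alone; adjusted p = 0.0275, and adjusted p = 0.180 with an estimated correlation). Fibroblast and stroma markers, which HepG2 cells should lack, were lower with 1 of 15 members called, PDGFRB (−0.24 ± 0.05), the same when adjusted over the list alone (adjusted p = 0.0296, and adjusted p = 0.360 with an estimated correlation). In the unfolded protein and integrated stress response list DNAJB9 (0.26 ± 0.05) and ATF4 (0.24 ± 0.06) rose and 0 fell (4 and 0 when adjusted over the list alone), with a median of 0.061 that went to −0.033 with housekeeping centring (adjusted p = 0.0194, and adjusted p = 0.360 with an estimated correlation). Housekeeping genes were higher as a list with 0 of 11 members called, also when adjusted over the list alone (adjusted p = 0.0194, and adjusted p = 0.180 with an estimated correlation). Their median was 0.085, and housekeeping centring brings it near 0 by design (−0.008).

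Without DMSO replicate 1 the adjusted p-values were 0.0564 for bile acid genes, 0.0923 for ribosome biogenesis genes, 0.0850 for the NF-kB list, 0.0529 for housekeeping genes and 0.113 for hepatocyte transcription factors. Hepatocyte transcription factors had 0.141 without RVX-208 replicate 3 and 0.0703 without RVX-208 replicate 2. Stroma markers had 0.0916 without RVX-208 replicate 3 and 0.0650 and 0.0510 without DMSO replicate 2 and 3, and ribosome biogenesis genes 0.0578 without DMSO replicate 2. Of single genes, ATF4, PDGFRB and CDC6 were each called in 0 of 8 fits without 1 array. Without RVX-208 replicate 3 they stood at 0.242, −0.243 and 0.191 (adjusted p = 0.138, 0.114 and 0.148 by limma). ABCA1 fell with RVX-208 as well (−0.44 ± 0.06), the only one of 17 apolipoprotein and lipoprotein genes to pass, also when adjusted over the list alone (list adjusted p = 0.680), with an adjusted p of 0.0638 without RVX-208 replicate 3. The APOA1 probe set gave 0.32 ± 0.51 with an interval of −0.86 to 1.49 (adjusted p = 0.716), which does not exclude a 2-fold rise. HepG2 cells are known to express APOA1 strongly, so this dim probe set is not taken as a measure of its transcript. The other 18 lists were not called; their adjusted p-values ran from 0.0735 for G1/S genes, with CCNE2 (0.29 ± 0.06) and CDC6 (0.22 ± 0.05) higher, to 0.964 for p53 targets. The test pointed up with a mean below 0 for apolipoprotein (median 0.014, mean −0.008), complement (0.016, −0.020) and oncofetal genes (0.012, −0.016).

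**Figure D2:**
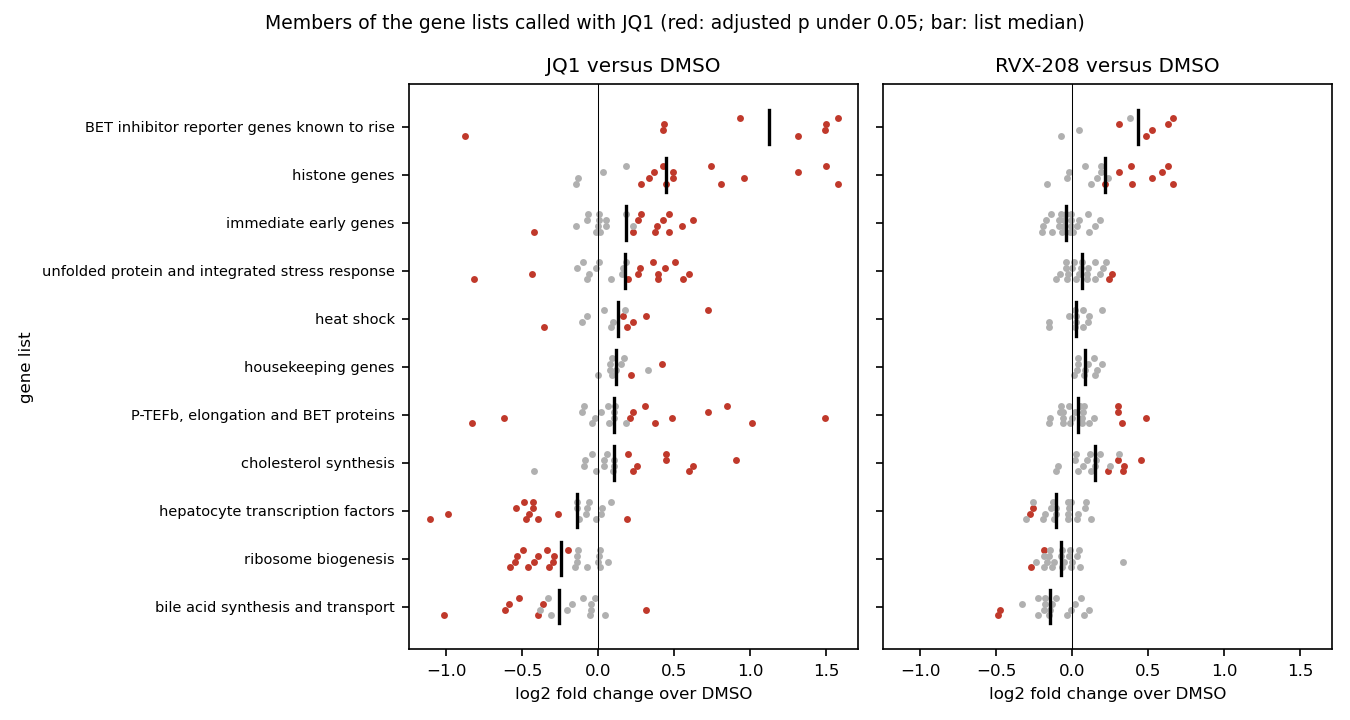
Log2 fold change of each member of the 11 lists called with JQ1, for JQ1 and RVX-208 against DMSO; red points have an adjusted p under 0.05 and bars are list medians. The histone list shows 13 of 17 members higher with JQ1 and 8 of 17 with RVX-208. With arrays centred on housekeeping genes the JQ1 medians of cholesterol synthesis, P-TEFb and heat shock genes go below 0. So do the RVX-208 medians of stress response, heat shock and P-TEFb genes. The housekeeping medians lie near 0 there by design.

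JQ1 and RVX-208 were then set against each other, at doses that differ. Their log2 fold changes went largely the same way. Of the genes called with both compounds in the same direction, 629 of 789 had the larger estimate with JQ1, and for 281 the difference was called. HEXIM1 was 1.01 ± 0.06 log2 units higher with JQ1 (interval 0.87 to 1.14, adjusted p = 1.210e-04), BRD2 0.69 ± 0.07 higher (0.53 to 0.85) and MYC 0.45 ± 0.06 lower (−0.59 to −0.31, adjusted p = 0.00273). CYP1A1 fell with JQ1 and rose with RVX-208, a difference of −2.32 ± 0.10 (−2.55 to −2.09, adjusted p = 4.181e-05), or 4.99-fold. In all, 1952 genes differed, 743 higher and 1209 lower with JQ1, and 27 of them at least 2-fold.

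ARRDC4 (1.43 ± 0.08), SLFN5 (1.38 ± 0.11), CNNM4 (1.29 ± 0.05), CDK11B (1.18 ± 0.25) and the arginine- and serine-rich protein gene RSRP1 (1.18 ± 0.07) stood highest in JQ1 relative to RVX-208. After CYP1A1, the lowest were ART4 (−1.70 ± 0.10), PALMD (−1.32 ± 0.08) and EREG (−1.29 ± 0.17). BDP1 was also among the named falls, but its mean log2 signal of 1.94 with JQ1 lay at the lowest values of those arrays (1.8187 and 2.063), so its fold is not given. Its call (adjusted p = 0.0450) held, of the fits without 1 array, only in that without RVX-208 replicate 3. The adjusted p was 0.204 and 0.141 without JQ1 replicate 1 and 2 and 0.0900 and 0.118 without RVX-208 replicate 1 and 2. Without DMSO replicate 1, 2 and 3 it was 0.0679, 0.0639 and 0.0643. CDK11B stood at 0.783 without JQ1 replicate 2 (adjusted p = 0.124) and at 0.994 without RVX-208 replicate 3 (adjusted p = 0.0523). The number of genes that differed was 841 and 949 without JQ1 replicate 1 and 2, and 1268, 1166 and 1169 without RVX-208 replicate 1, 2 and 3. Some genes gave no call of a difference. The difference was 0.00 ± 0.08 for SH3TC2 and −0.11 ± 0.06 for AKR1D1 (adjusted p = 0.272). SERPINI1 differed by 0.55 ± 0.16 with an interval of 0.18 to 0.93 (adjusted p = 0.0677). For BRD3 it was 0.10 ± 0.05 with an interval of −0.02 to 0.22, and for APOA1 0.01 ± 0.57 with an interval of −1.30 to 1.32.

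Of the lists, 7 differed between the compounds, 5 higher and 2 lower with JQ1; none did with an estimated correlation, where 5 had an unadjusted p under 0.05, and fry called 10. Immediate early genes were higher with JQ1, 9 of 23 members up and 0 down (10 and 1 when adjusted over the list alone; adjusted p = 6.122e-06, and adjusted p = 0.0681 with an estimated correlation). EGR1 (0.52 ± 0.07) and MCL1 (0.48 ± 0.06) were among those higher. Against DMSO, EGR1 and MCL1 stood at 0.10 and −0.01 with RVX-208, and the list was not called there (adjusted p = 0.658). Histone genes were higher, 9 of 17 up and 0 down (10 and 0 when adjusted over the list alone; adjusted p = 6.122e-06, and adjusted p = 0.157 with an estimated correlation), as were BET reporters known to rise, 5 of 8 up and 1 down (6 and 1 when adjusted over the list alone; adjusted p = 4.692e-04, and adjusted p = 0.157 with an estimated correlation). P-TEFb, elongation and BET genes were higher with 6 of 22 up and 2 down (7 and 3 when adjusted over the list alone; adjusted p = 0.00350, and adjusted p = 0.242 with an estimated correlation), POLR2A by 0.80 ± 0.07. Ribosome biogenesis genes were lower with JQ1, 8 of 22 down and 0 up (9 and 0 when adjusted over the list alone; adjusted p = 2.145e-05, and adjusted p = 0.293 with an estimated correlation). Hepatocyte transcription factors were lower too, 7 of 21 down and 0 up (8 and 1 when adjusted over the list alone; adjusted p = 0.00125, and adjusted p = 0.330 with an estimated correlation), HNF4G by −0.88 ± 0.06 and PROX1 by −0.81 ± 0.10. TGF-beta and matrix genes were higher, 5 of 18 up and 1 down (6 and 1 when adjusted over the list alone; adjusted p = 0.0491, and adjusted p = 0.242 with an estimated correlation); this call was kept in 7 of 17 settings. Its adjusted p was 0.0882 without RVX-208 replicate 1, 0.0748 and 0.0650 without JQ1 replicate 1 and 2, and 0.0639, 0.0580 and 0.0635 without DMSO replicate 1, 2 and 3. Cholesterol synthesis genes, called with each compound, did not differ as a list (median difference 0.011, adjusted p = 0.694), with IDI1 higher by 0.45 ± 0.07 in JQ1. Among lists not called, test and mean went apart for NF-kB (up, mean −0.003), acute phase (up, −0.019), fatty acid (up, −0.030), interferon (up, −0.018), stroma (up, −0.010) and complement genes (down, 0.013).

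Because both compounds were compared with the same DMSO arrays, part of the likeness of their fold changes is noise in common. Across genes, which are not independent replicates, the covariance of the log2 fold changes was 0.02686. It had a mean of 0.004570 and a maximum of 0.005379 in simulated data with no effect. The simulated noise was independent between genes, so this maximum is no bound for noise that genes share. The correlation was 0.645 (Spearman 0.647) against a simulated mean of 0.447 and maximum of 0.494, and 76.4% of genes had the same sign against 64.7%. Genes called with both compounds in the same direction numbered 789, 467 higher and 322 lower, where independent calls at the same rates, which leave the shared arrays out of account, would give 58.6 and 69.2. Their median size was 0.485 log2 units with JQ1 and 0.317 with RVX-208. Of 4066 genes called with JQ1, 90.5% had the same sign with RVX-208, against 58.6% in simulations with an effect of JQ1 alone. Among genes called with JQ1 that went the same way with RVX-208, 2 changed more with RVX-208 by the test of the difference, NID2 (−0.19 and −0.42) and THBS1 (−0.22 and −0.47), both matrix protein genes.

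The compounds moved 5 genes in opposite directions with a call in each: CYP1A1, CCN2, DET1, IFT70B and SYNM. CCN2, a matrix-associated target of TGF-beta and YAP signalling, rose by 0.51 ± 0.05 with JQ1 and fell by 0.28 ± 0.05 with RVX-208 (difference 0.79 ± 0.05, adjusted p = 2.022e-04). DET1 and IFT70B stood at −0.42 and −0.36 with JQ1 and at 0.30 and 0.39 with RVX-208, and SYNM at 0.40 and −0.19. With RVX-208 the adjusted p by limma was 0.0230 for CCN2, 0.0400 for DET1, 0.0201 for IFT70B and 0.0487 for SYNM. These calls lie closer to the threshold than that of CYP1A1 (0.00677), which held in 8 of 8 fits without 1 array. RVX-208 calls fell from 1120 to 52 without RVX-208 replicate 3, so the opposite directions of CCN2, DET1, IFT70B and SYNM are less certain. A further 326 genes were called with RVX-208 and not with JQ1, and for 46 of these the difference was called too, for example in PTGR2 (0.48 ± 0.08 against 0.06 ± 0.09), METTL1 (0.52 ± 0.11 against 0.04 ± 0.12) and MOG (−0.63 ± 0.13 against 0.04 ± 0.15). The RVX-208 call of MOG held in 3 of 8 fits without 1 array, with an adjusted p of 0.114 by limma without RVX-208 replicate 3. NID2, DET1, IFT70B, SYNM, PTGR2 and METTL1 were chosen after their values were seen.

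**Figure D3:**
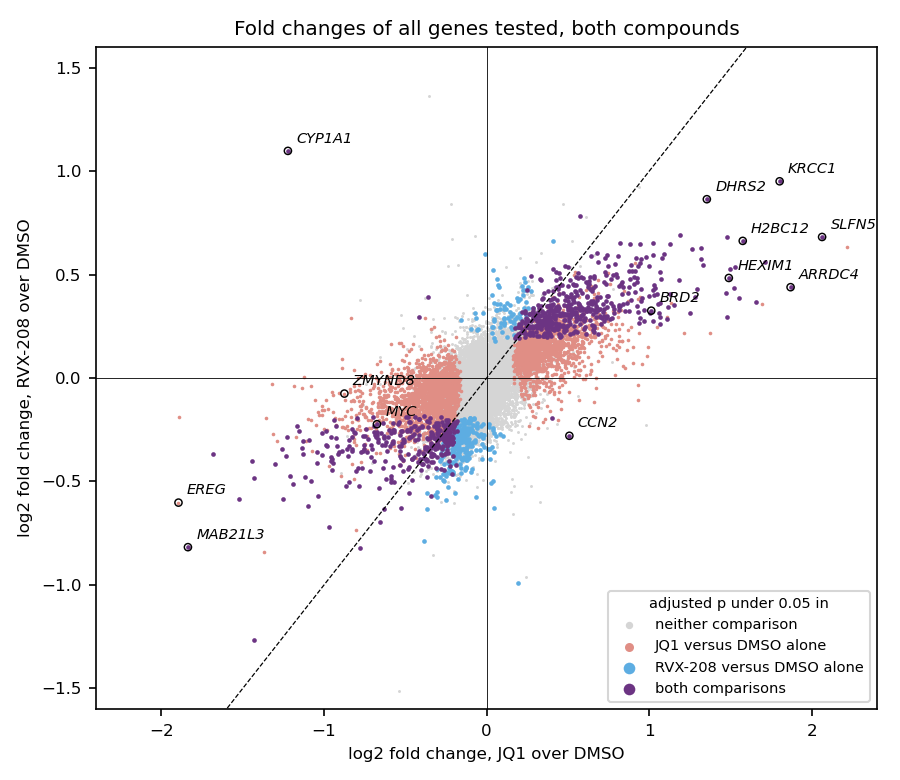
Log2 fold change of each gene with RVX-208 (vertical axis) against that with JQ1 (horizontal axis), with the line of equality dashed. Most points called with both compounds lie between the line and the horizontal axis, and CYP1A1 stands alone at −1.22 with JQ1 and 1.10 with RVX-208.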

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

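The tests under cyclic loess normalisation were chosen after the result was seen; the other alternatives were planned. Of the calls against DMSO, 10 of 11 lists and 81 of 95 named genes with JQ1, and 3 of 10 lists and 9 of 53 named genes with RVX-208, were past the threshold in every setting at the preset correlation. Between the compounds these were 6 of 7 lists and 11 of 13 named genes. All these counts are at an adjusted p under 0.05, and the other thresholds are not among the settings counted. The number of genes with JQ1 against DMSO went from 4066 to 8206 (960 higher) with arrays centred on housekeeping genes, 2203 at an adjusted p under 0.01, 667 at 1.5-fold or more, 6329 at an unadjusted p under 0.05, and 2565 to 3788 when 1 array was left out. With RVX-208 against DMSO it went from 1120 to 2035 without the 40% dimmest genes, where fewer genes are tested. It was 3397 (313 higher) with housekeeping centring, 2358 with an intensity trend and robust variances, 45 at an adjusted p under 0.01, 41 at 1.5-fold, 4987 unadjusted, and 52 to 756 with 1 array left out. Between the compounds it went from 1952 (38.1% higher with JQ1) to 2276 (427 higher, 18.8%) with housekeeping centring, 754 at an adjusted p under 0.01, 255 at 1.5-fold, 4416 unadjusted, and 841 to 1981 with 1 array left out. Housekeeping centring moves every array by 1 value, which shifts all genes at once. Centring on the array median made 58.8% of JQ1 calls and 64.1% of RVX-208 calls rises, against 47.1% and 48.8%. With the replicate number as a block the counts were 3057, 80 and 1050. The numbers may not pair the samples, since deviations from the group mean in arrays of the same number correlated at only −0.150 to 0.076 and not every sample correlated best with its own number. Lists called by camera with an estimated correlation numbered 0 in each comparison, with 6, 6 and 5 at an unadjusted p under 0.05 and 16, 14 and 10 by fry. Lists with RVX-208 went from 10 to 5 without the dimmest genes, 6 with housekeeping centring, 6 after quantile normalisation, 6 after cyclic loess, and 5 to 12 with 1 array left out. Between the compounds 11 lists in place of 7 were called with the intensity trend and robust variances. The covariance of the fold changes was 0.03077 without the dimmest genes and 0.02539 to 0.03169 with 1 array left out. No called gene among those named by rule changed sign. With housekeeping centring the JQ1 medians of the called cholesterol synthesis, P-TEFb and heat shock lists went below 0. So did the RVX-208 median of the called stress response list. Those of the housekeeping list went below 0 too, but that centring sets them near 0 by design. Camera, which compares a list with the other genes, kept its direction. Where no reason is given, the cause was not tested. The signal of dim genes over background limits what can be seen for genes such as APOA1.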

Other observations

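The gene families and the tests of explanations reported here were chosen after the result was seen. The fixed gene lists, the simulation of shared controls and the fits without 1 array were planned. Genes for zinc finger proteins, many of them repressors of transcription, stood higher as a family with both compounds by camera at its preset correlation (adjusted p = 0.00426 with JQ1 and 2.279e-05 with RVX-208 over 47 families), and not with an estimated correlation (0.684 and 0.405). Of all 17845 genes, 1916 rose and 2150 fell with JQ1, and 546 rose and 574 fell with RVX-208. Of 474 genes with the symbol root ZNF, 118 rose and 67 fell with JQ1, and 31 rose and 4 fell with RVX-208. With arrays centred on housekeeping genes, which shifts all genes at once, the majority turned. Then 87 were higher and 140 lower with JQ1, and 24 higher and 31 lower with RVX-208. The family was still called against other genes by camera at its preset correlation (adjusted p = 3.112e-05 and 3.042e-07). ZNF43 rose by 1.02 with JQ1 and 0.65 with RVX-208, ZNF280C by 1.02 and 0.59, and ZNF10 by 1.05 and 0.40, while ZNF114 fell by 1.26 and 0.34. The family median was 0.064 with JQ1 and 0.062 with RVX-208, and went to −0.093 and −0.032 with that centring. With JQ1 it was 0.040 without DMSO replicate 3, and 0.054 and 0.056 without JQ1 replicate 1 and 2. With RVX-208 the number that rose was 1 without RVX-208 replicate 3, 2 without DMSO replicate 3, 7 and 11 without RVX-208 replicate 2 and 1, and 18 without DMSO replicate 2. With any 1 array left out the adjusted p of the family was at most 0.0200 with JQ1 and 5.792e-04 with RVX-208.

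Small nucleolar RNA genes of the SNORD root also stood higher (adjusted p = 4.012e-05 with JQ1 and 4.568e-05 with RVX-208), and not with an estimated correlation (0.772 and 0.405). Of 113 such genes, 25 rose with JQ1 and 8 with RVX-208, and 0 fell with either by limma (2 and 3 lower at an unadjusted p under 0.05). With housekeeping centring 15 were higher and 16 lower with JQ1, and 8 higher and 4 lower with RVX-208. The family was still called with that centring by camera at its preset correlation (adjusted p = 4.871e-08 and 9.576e-08). The family median was 0.151 with JQ1, −0.006 with that centring, 0.075 without JQ1 replicate 1 and 0.087 without DMSO replicate 3. With RVX-208 it was 0.111, 0.018 with that centring and 0.050 without DMSO replicate 3. SNORD59A rose by 0.78 and 0.50 and SNORD59B by 0.64 and 0.59 with JQ1 and RVX-208. Copies of SNORD116, which lie at a single locus and are not independent, made up 11 of the 25. The 25 became 13 without JQ1 replicate 1, where the family had an adjusted p of 0.00988. With RVX-208 the 8 became 0 by limma without DMSO replicate 3, RVX-208 replicate 2 or RVX-208 replicate 3, where 17, 20 and 20 were higher at an unadjusted p under 0.05, 4 without DMSO replicate 2 and 5 without DMSO replicate 1 or RVX-208 replicate 1.

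Mitochondrial ribosome genes of the MRPL root were lower with JQ1 than with RVX-208, 8 of 47 with a call (median −0.119, adjusted p = 5.021e-04, 0.830 with an estimated correlation), or 14 with housekeeping centring (median −0.183). Against DMSO the family was not called (median −0.047, adjusted p = 0.255 with JQ1; 0.028 and 0.0589 with RVX-208). MRPL46 was lower by 0.45 and MRPL50 by 0.35. Their median was −0.077 without JQ1 replicate 2, and their number was 3 without JQ1 replicate 1 or 2 and 4 without RVX-208 replicate 1, 2 or 3. The ZNF, SNORD and MRPL roots were picked out of 47 symbol roots with at least 30 genes, after other sets such as aryl hydrocarbon receptor targets, growth factor ligands and protein subunit families had been looked at. Camera called 7 roots with JQ1, 15 with RVX-208 and 1 between the compounds, and none with an estimated correlation. After cyclic loess 2, 8 and 1 of these were still called. Among the others, the RPS root had adjusted p = 0.00426 with JQ1 and 8.379e-04 with RVX-208 (medians 0.074 and 0.059, but −0.084 and −0.035 with housekeeping centring). This root takes genes of the small ribosomal subunit and any other gene whose symbol starts with the same letters. The RPS call with JQ1 was lost with that centring (0.0818), after quantile normalisation (0.0660) and after cyclic loess (0.0528). The COL root had a median of −0.146 with RVX-208 (adjusted p = 2.279e-05), which was −0.066 after cyclic loess, −0.079 after quantile normalisation and −0.240 with housekeeping centring.

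Many dim genes read lower with both compounds than with DMSO. The median log2 fold change of 349 olfactory receptor genes, which HepG2 cells are not known to express, was −0.066 with RVX-208 and −0.072 with JQ1. Over all genes it was −0.023 and −0.040, and camera did not call this family (adjusted p = 0.0589 and 0.356). The dimmest genes, at mean log2 signals of 2.41 to 4.49, had −0.038 and −0.037. Those at 5.99 to 6.65 had −0.116 and −0.085. The RVX-208 arrays alone differed by 0.072 in the olfactory receptor median, close to the 0.076 between the means of the DMSO and RVX-208 groups. An intensity-dependent difference between arrays left after normalisation may therefore account for the RVX-208 values. For JQ1 this was not tested. Such a difference is also a candidate explanation for part of the RVX-208 calls of housekeeping, NF-kB and stroma genes. After cyclic loess normalisation their medians went from 0.085 ± 0.062 (SD over members) to 0.060 ± 0.057, from −0.123 ± 0.163 to −0.071 ± 0.157 and from −0.136 ± 0.100 to −0.060 ± 0.102. The middle of the 3 sizes after was 48.6% of the middle one before, which belonged to another list. The camera calls of these lists ended at adjusted p = 0.171, 0.0525 and 0.175. The stress response call ended too (0.102) with its median at 0.061 before and after, so the explanation is not put forward for it, and the bound of the test was set once these values were known. Histone, cholesterol synthesis and BET reporter genes (4 of the 8 reporters are histone list members) went from 0.218 to 0.248, from 0.152 to 0.122 and from 0.432 to 0.423 (the middle size after being 114% of that before) and stayed called, which argues against intensity as their whole cause; loess would also remove a change in the cells that follows expression level, so that stays open.

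The fold changes of JQ1 and RVX-208 share their direction. Noise in the DMSO arrays that both comparisons share, simulated as independent between genes, leaves 0.02229 of the covariance of 0.02686 unexplained. Noise that many genes share was not simulated. The covariance was 0.0252 after cyclic loess. These values argue against independent noise or intensity as the whole cause of the shared direction. Inhibition of BET proteins by both compounds, weaker for RVX-208 at the doses used, may account for it, as 5 of 8 reporters known to rise were called higher with RVX-208, although of 8 known to fall MYC alone was called lower, with adjusted p = 0.183 for that list, and single arrays decide some calls: H2BC12 had adjusted p = 0.0892 and 0.0577 without RVX-208 replicate 3 and 2 and 0.0630 and 0.0800 without DMSO replicate 2 and 3, H2BC5 had 0.0529, 0.0611 and 0.0838 without RVX-208 replicate 1, 2 and 3, and the MYC call was lost without any 1 of the DMSO or RVX-208 arrays (at most 0.153). Handling that differed between DMSO and compound dishes stays open, since the labels used here name no dates or batches. Of the 10 splits of the 6 RVX-208 and DMSO arrays, 1 (the real one) gave 1120 genes and the highest other gave 0 by limma; 10 splits are too few for a share under 0.05.

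CYP1A1 fell with JQ1 and rose with RVX-208. Cross-reading of transcripts of the paralog CYP1A2 would need that gene to move alike, and the 95% interval of its difference ran from −0.300 to 0.063 against −2.32 for CYP1A1. An array out of place is argued against by the gap of 2.051 between the lowest RVX-208 and the highest JQ1 array, and by an adjusted p of at most 8.745e-04 with any 1 array left out. Opposite effects of the compounds on the aryl hydrocarbon receptor might give such a pattern, but 0 of 7 other targets of that receptor were called lower with JQ1 than with RVX-208 by limma, 1 was lower at an unadjusted p under 0.05, and TIPARP was higher by 0.64. Targets that JQ1 moves by another route, or that respond little at 4 h, keep this open.

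The table of the authors gives HEXIM1 a log2 ratio of 1.354 with JQ1, where the deposited values give 1.490, with an F of 334.0 in both.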
